A study of Rattus norvegicus with 12 samples.

How the data were processed

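Messenger RNA from the kidney cortex of male rats aged 6 weeks was sequenced in 12 libraries, 4 from wild-type rats (WT), 4 from rats with 1 mutated Xdh allele (HET) and 4 from rats with both alleles mutated (HOMO), per the labels. Groups and replicate numbers were taken from the sample titles. The HET replicates carry the numbers 1, 2, 4 and 5, and the other groups carry 1 to 4. The groups were littermates, per the series design, but the labels do not state that each library came from a different animal. If some did not, the p-values measure only the spread between these samples, which may be technical. RNA was extracted with Trizol from frozen tissue and libraries were made with a stranded mRNA kit, per the labels' protocols.

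The gene-level values came as raw read counts per gene in a table the authors deposited, for 32623 genes identified by Ensembl identifiers and symbols. The submitters' processing notes name genome build Rnor_6.0 and edgeR 3.8.6 without saying what each was used for. The aligner, the counter, the annotation and the use of strand in counting are not given in the sources used here. The same table held RPKM values by the authors. A count divided by the listed gene length and the library total gave them with a median deviation of 0.0416% and a largest deviation of 2.13% among values with at least 50 counts, so the RPKM values carried no further information and were used only for that check. The authors also deposited comparison tables with log2 fold changes, p-values and false discovery rates for the 3 pairs of groups. Their raw count columns differed from the count table in 0 values. Fold changes and calls from those tables are named as the authors' wherever they are printed. The listed genomic interval was shorter than the listed gene length for 70.5% of genes, so listed ends are not used as gene ends. Reads from near-identical genes, and from overlapping genes on opposite strands, may have been split or shared by the authors' counting. Members of the RT1 and kallikrein families, the Akr1c and Cyp4a genes and the olfactory receptor Olr1668 are therefore uncertain.

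Genes were kept with filterByExpr (minimum count 10, minimum total count 15), which left 15856 of the 22687 genes with a count in any library. Composition factors were computed by TMM, and 1 negative binomial model with a term per genotype was fitted to all 12 libraries in edgeR 4.0.16 (R 4.3.3), with robust quasi-likelihood dispersion. All adjusted p-values of genes are from its quasi-likelihood F-test with Benjamini-Hochberg adjustment over the genes tested in a comparison, at a level of 0.05, and "rose", "fell" and "called" refer to that level. Levels are TMM-scaled CPM from edgeR, given as mean ± SD over 4 libraries, and log2 fold changes are given with their standard error. A total of 34 gene lists, with 628 members of which 588 were tested, was fixed before the data were examined, as were the comparisons, the rule for naming genes and the alternatives. The symbols of 18 list members were not matched and those genes are not analysed here. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the 34 lists. Camera with an estimated correlation and fry were run as alternatives. Values of single measures per library were compared by exact two-sided permutation tests over all 70 arrangements, with a smallest possible p of 0.0286. These were added after the data were seen, and 9 such tests were adjusted together. The simulation and split of the HOMO libraries for the overlap of their comparisons were also added then.

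The rule named Xdh, the 10 called genes with the largest rise and the 10 with the largest fall among those with an average log2 CPM of at least 1, a named symbol and no overlap between groups, and 3 members of each list by p-value plus 1 that went against its median. Most of these are given for HOMO against WT, and some genes the rule names are not reported here. For the other comparisons, a smaller set was chosen after the data were seen: Xdh and the largest changes for HOMO against HET, and Xdh and members of the lists that camera called for HET against WT. A gene with 0 counts in a group is given as a bound against a floor of 3 counts over the group, and a gene with 1 to 3 counts as a ratio of summed counts with an exact 95% interval. Both cover counting error only. The genes of straight and convoluted segments, fat and urothelium were chosen from textbook knowledge after the data were seen, and LOC100909505 was named after its values were seen.

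Alternatives were RLE composition factors, library size alone, no filter, a filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma voom, only the 8 libraries compared, the replicate number as a block, glmTreat against a fold of 1.5, a level of 0.01 and leaving out each library. Others were added after the data were seen: leaving the library labelled HOMO replicate 3 out of HET against WT, leaving out HOMO replicate 1 with HET replicate 1, and a covariate for straight-segment genes. Library totals ran from 18995464 to 37023629 counts, and 3 counts corresponded to between 0.0601 and 0.184 CPM. No pair of libraries of 1 group came close to sampling noise, since the chi-square statistic per degree of freedom was 19.6 or more.

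The search for libraries far from their group used Dixon's ratio with a critical value of 0.829 for 4 samples, and groups whose values all lay at or under 3 counts were left out, a choice made after the data were seen. A change of sign of a gene called under neither setting was not counted as a reversal, also a later choice. The procedure was tested on simulated data with known changes drawn from the real means, library sizes and dispersions, after a first fit of the real data. For HOMO against WT it recovered 38.8% of 67 genes changed by 1.5-fold, 71.6% of 67 changed by 2-fold and 92.4% of 66 changed by 4-fold among 14828 genes, and 13 of the 148 calls (8.78%) were of unchanged genes. For HET against WT, recovery was 38.8%, 67.2% and 97.0% among 14808 genes, with 5.59% of calls false. For HOMO against HET it was 43.3%, 74.6% and 93.9% among 14823 genes, with 4.08% false. The simulated counts were independent draws per gene, without structure shared across genes within a library. These rates may therefore not hold for the real comparisons, HET against WT included.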

Results

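Gene expression was measured by RNA sequencing in the kidney cortex of male rats aged 6 weeks that carried 0, 1 or 2 mutated alleles of Xdh, the gene of xanthine dehydrogenase, which forms uric acid from hypoxanthine and xanthine. Each genotype, WT, HET and HOMO, had 4 libraries. Total counts ran from 28481944 to 36119168 in WT, from 18995464 to 37023629 in HET and from 22858907 to 36998378 in HOMO. The first principal component held 80.8% of the variance of log2 CPM and separated the 4 HOMO libraries (118 to 142) from the 8 others (-75.0 to -53.5). Correlations of log2 CPM across genes, which are not independent replicates, were 0.972 to 0.990 within a group, 0.974 to 0.990 between WT and HET libraries and 0.813 to 0.869 between HOMO and the others.

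Xdh (ENSRNOG00000007081, listed on chromosome 6 of Rnor_6.0 from position 25149235) was measured in every library. Its level was 281, 380, 212 and 270 CPM in WT replicates 1 to 4, and 182, 197, 140 and 158 CPM in HET replicates 1, 2, 4 and 5. In the HOMO group it was 61.7, 60.7 and 57.6 CPM in replicates 1, 2 and 4, but 230 CPM in the library labelled HOMO replicate 3, which lay within the WT range and against its label. The group levels were 286 ± 69.7, 170 ± 25.3 and 102 ± 84.9 CPM (SD, n = 4). Xdh was lower in HOMO than in WT by a log2 fold change of -1.48 ± 0.43 (edgeR adjusted p = 0.0101), but the exact permutation p of the CPM values was 0.0571 (adjusted 0.0857), and with library size alone the edgeR value was -0.85 (adjusted p = 0.0901). Over the other settings that left out no WT or HOMO library the adjusted p lay between 0.00102 and 0.0251. Without the library labelled HOMO replicate 3 the HOMO level was 60.0 ± 2.15 CPM (n = 3), 21.0% of the WT mean, and the log2 fold change -2.25 (adjusted p = 5.40e-07). The HET mean was 59.4% of the WT mean, with a log2 fold change of -0.75 ± 0.43 that was not called over all genes (adjusted p = 1). Each HET library lay below each WT library, with an exact permutation p of 0.0286, the smallest possible, and 0.0514 after adjustment.

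**Figure D1:**
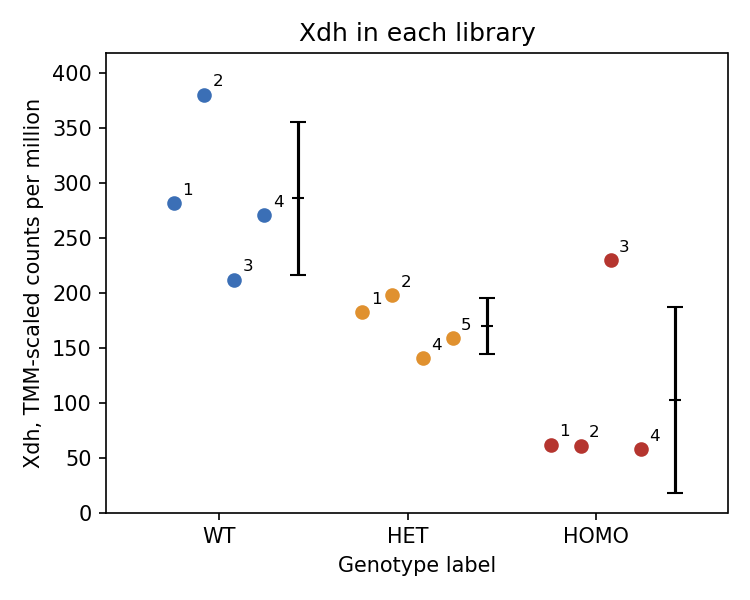
Xdh level in TMM-scaled CPM (vertical axis) for each library, by genotype label (horizontal axis), with replicate numbers beside the points and the mean ± SD (n = 4) as black bars. The 3 other HOMO libraries sit between 57.6 and 61.7 CPM, and the library labelled HOMO replicate 3 at 230 CPM.

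The comparison of HOMO with WT addressed how loss of xanthine dehydrogenase changes the kidney cortex. Transcripts of the proximal tubule, of its transporters and of mitochondrial respiration were lower in HOMO, and those of tubular injury, extracellular matrix and immune cells were higher. The phosphate transporter Slc34a1 went from 4372 CPM in WT to 229 ± 15.0 CPM in HOMO, and the epidermal growth factor gene Egf from 176 to 1.30 ± 0.469 CPM. The injury marker Lcn2 went from 4.10 to 518 ± 95.2 CPM and the chaperone Clu from 79.2 to 1718 ± 166 CPM. Of 15856 genes tested, 11369 (71.7%) were called, 5861 higher and 5508 lower, and 5804 of them by more than 2-fold. With library size alone as the scale, 10292 of 12856 called genes (80.1%, against 51.6%) were higher, the median of all genes was 0.65 and 987 genes called under both scales had opposite directions, so changes are given relative to the TMM scale. The HOMO and WT libraries did not overlap for 10524 genes (66.4%, where chance gives 2.86%). Without the library labelled HOMO replicate 3, 11339 genes were called. The authors' deposited table calls 9317 of the 13851 genes tested there, 4867 higher and 4450 lower, and all 9199 genes called both there and here had the same direction.

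Markers of the proximal tubule, the segment that reabsorbs most of the filtered solutes, fell in HOMO in 27 of 28 cases with 1 rise, at a median log2 fold change of -2.96 (camera adjusted p = 4.01e-11, and adjusted p = 0.0510 with an estimated correlation). Slc34a1 was at -4.26 ± 0.11, the gluconeogenic enzyme Fbp1 at -3.93 ± 0.12 and the inositol oxygenase Miox at -4.93 ± 0.15 (largest adjusted p = 7.71e-11). Cyp4b1 was the member that rose (0.74 ± 0.29, adjusted p = 0.0372). It lost its call without a filter and without WT replicate 2, 3 or 4 or HOMO replicate 3 or 4, and its log2 fold change was then between 0.55 and 0.75. All 14 tested genes of urate and organic anion transport fell, at a median of -3.13 (camera adjusted p = 5.52e-06, and 0.0510 as the adjusted p with an estimated correlation). Among them the scaffold protein Pdzk1 fell by 3.48 ± 0.12 and the organic anion transporters Slc22a6 by 4.45 ± 0.17 and Slc22a8 by 3.75 ± 0.19 (largest adjusted p = 2.23e-09). Of 24 genes of amino acid and gluconeogenic metabolism, 22 fell, 1 rose and 1 was not called (median -3.19, camera adjusted p = 8.55e-10, and adjusted p = 0.0510 with an estimated correlation). Dopa decarboxylase Ddc was at -4.78 ± 0.17 and D-amino acid oxidase Dao at -4.24 ± 0.15 (largest adjusted p = 1.87e-10), and Pck2 rose (0.32 ± 0.09, adjusted p = 0.00588). Adjusted over the list alone, the counts were as given for all of the 34 lists except inflammasome genes, and the lists held 519 such calls.

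Further along the nephron, thick ascending limb genes fell in 8 of 11 cases with 1 rise and 2 not called, at a median of -1.18 (camera adjusted p = 0.0142, and adjusted p = 0.395 with an estimated correlation). Egf was at -7.06 ± 0.21 and the tight junction gene Cldn10 at -3.71 ± 0.27 (largest adjusted p = 1.34e-07). The prostaglandin receptor Ptger3 rose (0.37 ± 0.14, adjusted p = 0.0262) but lost its call without any 1 of WT replicates 1, 2 and 4 and HOMO replicates 2 and 3, at values of 0.28 to 0.35. All 11 intercalated cell genes fell (median -1.24, camera adjusted p = 3.15e-04, and adjusted p = 0.257 with an estimated correlation). They included the ammonium transporter Rhbg (-2.09 ± 0.13), the proton pump subunit Atp6v1b1 (-1.70 ± 0.12) and Aqp6 (-2.40 ± 0.18). Distal convoluted and connecting tubule genes fell in 7 of 9 cases with 1 rise and 1 not called, without a camera call of the list (median -0.74, camera adjusted p = 0.0822, and adjusted p = 0.568 with an estimated correlation). The kallikrein Klk1 was at -6.91 ± 0.53 and, without the library labelled HOMO replicate 3, at -7.74. Calb1 fell by 2.64 ± 0.45 and the kinase Wnk1 by 0.99 ± 0.21, which lost its call with library size alone (-0.38, adjusted p = 0.0906). The calcium channel Trpv5 rose (1.38 ± 0.36, adjusted p = 0.00491).

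The lists of the collecting duct, podocytes and endothelium had no camera call, and their median log2 fold changes of -0.46, -0.28 and -0.42 turned to 0.16, 0.33 and 0.18 with library size alone. Collecting duct principal cell genes comprised 2 higher, 6 lower and 2 not called (camera adjusted p = 0.251, and adjusted p = 0.568 with an estimated correlation), with Fxyd4 at -2.05 ± 0.29 and the transcription factor Gata3 and the water channel Aqp4 at 0.97 ± 0.17 and 1.37 ± 0.25. Podocyte genes comprised 5 higher, 6 lower and 1 not called (camera adjusted p = 0.835, and adjusted p = 0.939 with an estimated correlation). The transcription factor Tcf21 (0.94 ± 0.19) and Kirrel1 (1.80 ± 0.21) rose, and Nphs1, a slit diaphragm protein, fell (-1.22 ± 0.20). Endothelial genes comprised 2 higher, 7 lower and 2 not called (camera adjusted p = 0.291, and adjusted p = 0.704 with an estimated correlation). Erg rose (0.81 ± 0.10) and Emcn fell (-1.32 ± 0.19). Ehd3 fell (-1.001 ± 0.18), a call lost with library size alone (-0.40, adjusted p = 0.0724). Cdh5 rose (0.39 ± 0.15, adjusted p = 0.0358) and lost its call without any 1 of WT replicates 2, 3 and 4 and HOMO replicates 1, 2 and 4, at values of 0.26 to 0.40.

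Genes of oxidative phosphorylation fell in all 32 tested cases, at a median of -1.51 (camera adjusted p = 1.29e-14, and adjusted p = 0.171 with an estimated correlation). The succinate dehydrogenase subunits Sdhc and Sdhb fell by 1.78 ± 0.07 and 1.56 ± 0.07, and the ATP synthase subunit Atp5f1a by 1.88 ± 0.08 (largest adjusted p = 9.84e-10). Transcripts of the mitochondrial genome made up 15.2 ± 1.23% of counts in WT, 15.8 ± 2.37% in HET and 6.43 ± 0.353% in HOMO (SD, n = 4), with an exact permutation p of 0.0286 for HOMO against WT (adjusted 0.0514). The 10 most abundant genes of a library took 18.0 ± 1.31% of counts in WT and 8.60 ± 0.334% in HOMO, with the same exact p. Fatty acid oxidation and peroxisome genes fell in 25 of 27 cases and 2 were not called (median -1.37, camera adjusted p = 4.85e-08, and adjusted p = 0.238 with an estimated correlation). The dehydrogenase Acadm and the flavoprotein Etfa were at -2.40 ± 0.12 and -1.65 ± 0.09, and the kinase Pdk4 was at 1.01 ± 0.69 (adjusted p = 0.210). Glycolytic genes went both ways, with 7 higher, 8 lower and 2 not called, and the median (0.20) and mean (0.08) had the opposite sign to the test (camera direction lower, adjusted p = 0.762, and adjusted p = 0.908 with an estimated correlation). Pgk1, Eno1 and Pgam1 fell by 1.34 ± 0.10, 1.77 ± 0.14 and 0.97 ± 0.09, and the lactate transporter Slc16a3 rose (2.85 ± 0.25).

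**Figure D2:**
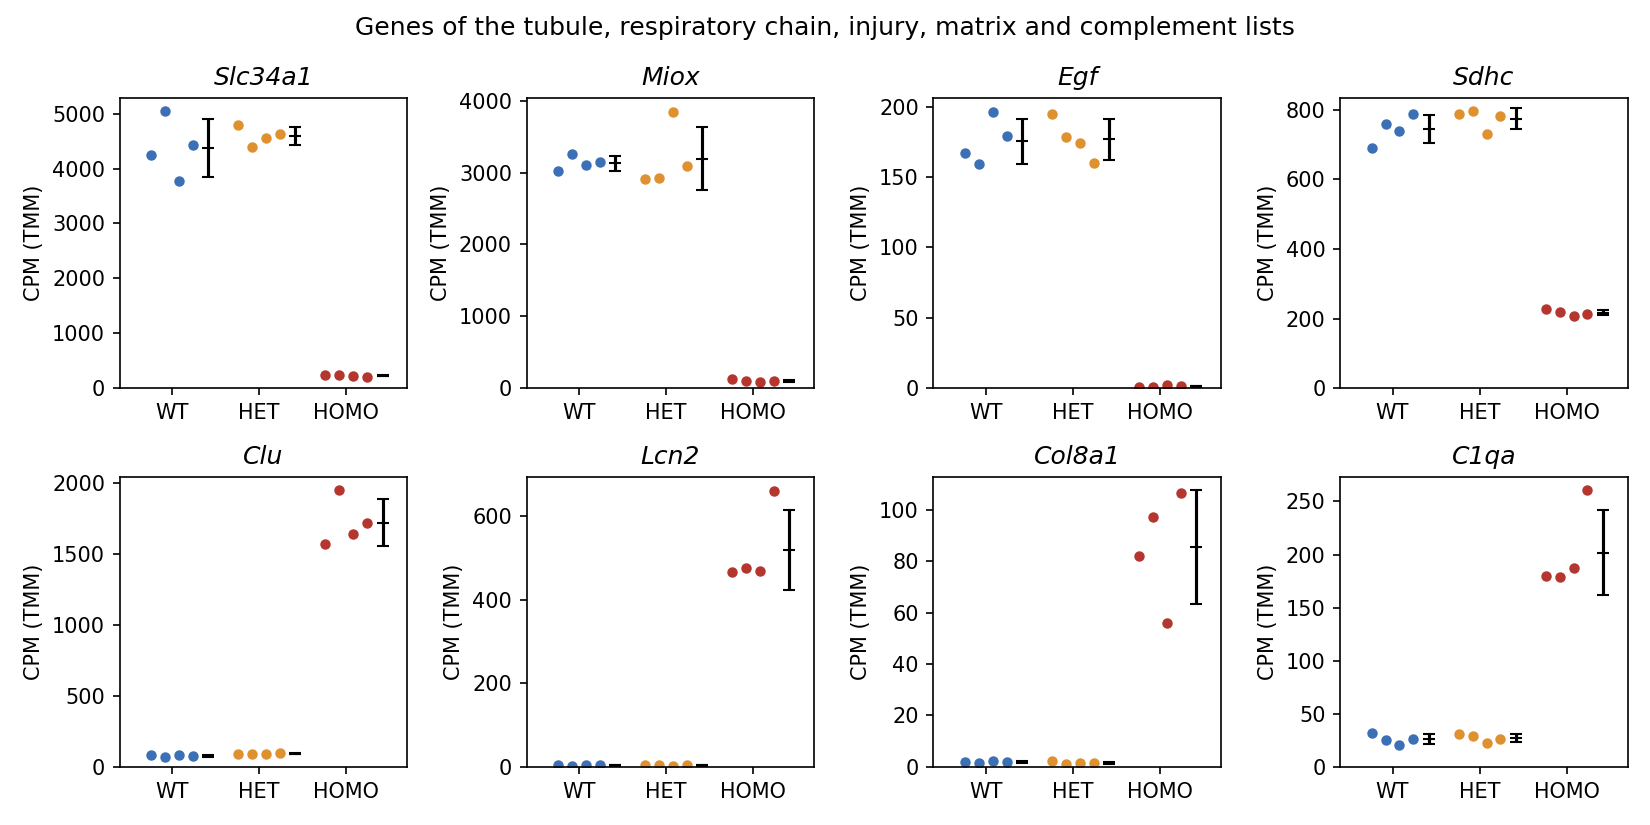
Level in TMM-scaled CPM (vertical axes) of 8 genes in each of the 12 libraries, by genotype (horizontal axes), with the mean ± SD (n = 4) as black bars. Slc34a1, Miox, Egf and Sdhc were lower and Clu, Lcn2, Col8a1 and C1qa higher in each HOMO library than in each WT and HET library. The falls did not flip with library size alone, and the rises could not, since that scale moves all genes upward.

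Tubular injury markers rose in 22 of 24 cases, with 1 fall and 1 not called, at a median of 3.26 (camera adjusted p = 2.49e-08, and adjusted p = 0.0688 with an estimated correlation). Clu rose by 4.44 ± 0.10, the adhesion receptor Cd44 by 4.49 ± 0.12 and Lcn2 by 6.97 ± 0.23 (largest adjusted p = 1.93e-10). The trefoil factor Tff3 fell (-5.18 ± 1.20, adjusted p = 0.00309). All 27 collagen and extracellular matrix genes rose (median 3.20, camera adjusted p = 3.13e-09, and adjusted p = 0.235 with an estimated correlation), among them Col8a1 by 5.51 ± 0.24, decorin Dcn by 2.75 ± 0.17 and lysyl oxidase Lox, a collagen cross-linking enzyme, by 4.14 ± 0.24 (largest adjusted p = 1.70e-08). Fibroblast and pericyte genes rose in 15 of 16 cases and 1 was not called (median 1.82, camera adjusted p = 9.20e-05, and adjusted p = 0.235 with an estimated correlation). S100a4 rose by 3.03 ± 0.19 and the growth factors Tgfb1 and Tgfb3 by 2.31 ± 0.20 and 2.54 ± 0.22.

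Immune cell genes were higher in HOMO. All 20 macrophage and monocyte genes rose (median 2.92, camera adjusted p = 7.14e-09, and adjusted p = 0.198 with an estimated correlation), with Lyz2 at 2.99 ± 0.16, Cd14 at 3.17 ± 0.17 and the mannose receptor Mrc1 at 4.65 ± 0.23. T and natural killer cell genes comprised 17 higher, 1 lower and 3 not called (median 1.91, camera adjusted p = 2.24e-04, and adjusted p = 0.235 with an estimated correlation). Cd3g, Cd4 and Cd5 rose by 3.24 ± 0.26, 2.41 ± 0.19 and 3.12 ± 0.27, and the granzyme Gzma fell (-1.66 ± 0.44, adjusted p = 0.00422). All 10 B and plasma cell genes rose (median 2.91, camera adjusted p = 0.00109, and adjusted p = 0.171 with an estimated correlation), including Cd22 (2.88 ± 0.30), Fcrla (2.38 ± 0.28) and the joining chain Jchain (3.55 ± 0.41). Neutrophil and mast cell genes rose in 9 of 10 cases and 1 was not called (median 4.32, camera adjusted p = 6.03e-04, and adjusted p = 0.171 with an estimated correlation). The calgranulins S100a8 and S100a9 rose by 6.17 ± 0.40 and 6.25 ± 0.43 and the receptor Kit by 1.46 ± 0.11.

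Genes of inflammatory signalling followed. Chemokines and cytokines comprised 19 higher, 1 lower and 8 not called (median 2.29, also with the 1 member at 0 counts in WT set to its bound; camera adjusted p = 8.82e-04, and adjusted p = 0.140 with an estimated correlation). The cytokine Lif rose by 3.48 ± 0.21 and the lymphoid chemokine Ccl21 by 4.63 ± 0.27, and Ccl5 fell (-0.75 ± 0.22), a call lost with library size alone (-0.13, adjusted p = 0.587). Inflammasome genes rose in 11 of 12 cases, and in 12 adjusted over the list alone (median 1.59, camera adjusted p = 2.53e-04, and adjusted p = 0.198 with an estimated correlation). The pore-forming Gsdmd, the adaptor Pycard and Il1b rose by 2.12 ± 0.14, 1.84 ± 0.14 and 3.51 ± 0.27. Complement genes rose in 18 of 20 cases and fell in 2 (median 2.92, camera adjusted p = 1.82e-06, and adjusted p = 0.171 with an estimated correlation), with Cfi and C1qa at 4.03 ± 0.17 and 2.95 ± 0.16 and C5 at -1.13 ± 0.20. All 14 antigen presentation genes rose (median 1.46, camera adjusted p = 5.69e-05, and adjusted p = 0.269 with an estimated correlation). The proteasome subunit Psmb10 rose by 1.89 ± 0.15, and RT1-Da and RT1-Db1, members of a polymorphic family whose counts are uncertain, by 1.72 ± 0.15 and 1.63 ± 0.14. Interferon response genes rose in 11 of 20 cases and 9 were not called (median 0.59, camera adjusted p = 0.0224, and adjusted p = 0.568 with an estimated correlation), and the camera call was lost without HOMO replicate 2 (adjusted p = 0.0512). Irf1, Gbp5 and Irf8 rose by 1.65 ± 0.14, 1.58 ± 0.17 and 1.45 ± 0.18.

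In purine metabolism and salvage, 7 genes rose, 12 fell and 5 were not called, and the median of -0.20 turned to 0.41 with library size alone (camera adjusted p = 0.403, and adjusted p = 0.501 with an estimated correlation). Guanine deaminase Gda, which forms xanthine, rose by 3.21 ± 0.13, Impdh2 by 1.21 ± 0.05 and Nt5c by 1.13 ± 0.10, and the nucleotidase Nt5e fell by 1.73 ± 0.10 (largest adjusted p = 5.82e-07). Antioxidant defence comprised 4 higher, 16 lower and 2 not called (median -1.002, camera adjusted p = 0.00178, and adjusted p = 0.257 with an estimated correlation). Sod1, the glutathione peroxidase Gpx3 and Gsr were at -2.14 ± 0.09, -3.30 ± 0.17 and -1.39 ± 0.09. NADPH oxidase and nitric oxide genes comprised 9 higher, 3 lower and 3 not called (median 1.59, camera adjusted p = 0.0822, and adjusted p = 0.424 with an estimated correlation). The renal oxidase Nox4 fell by 3.37 ± 0.17, Ddah1 by 2.47 ± 0.14 and Cyba by 1.04 ± 0.14, and Ddah2 rose (0.99 ± 0.06). Immediate early genes comprised 8 higher and 6 not called (median 1.38, camera adjusted p = 0.00864, and adjusted p = 0.487 with an estimated correlation). Atf3, Myc and Ier3 rose by 2.92 ± 0.23, 2.46 ± 0.21 and 1.72 ± 0.19, and Zfp36 was at -0.73 ± 0.56 (adjusted p = 0.268).

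Vitamin D, calcium and phosphate genes comprised 2 higher, 11 lower and 5 not called (median -1.18, camera adjusted p = 0.00148, and adjusted p = 0.0510 with an estimated correlation). The parathyroid hormone receptor Pth1r and Klotho, Kl, fell by 2.82 ± 0.12 and 2.98 ± 0.18, and the phosphate transporter Slc34a2 rose (4.38 ± 0.68). Renin angiotensin aldosterone genes comprised 2 higher, 9 lower and 5 not called, and the median of -0.61 lay at 0.00267 with library size alone (camera adjusted p = 0.0507, and adjusted p = 0.171 with an estimated correlation). The peptidases Enpep and Anpep were at -2.41 ± 0.10 and -3.82 ± 0.27, and Ctsz and the converting enzyme Ace rose (2.65 ± 0.15 and 2.90 ± 0.44). Urea and osmolyte genes comprised 2 higher, 3 lower and 4 not called, and the median (0.09) differed in sign from the mean (-0.22) and the test (camera adjusted p = 0.765, and adjusted p = 0.824 with an estimated correlation). The aquaporins Aqp11 and Aqp7 fell by 3.23 ± 0.08 and 1.83 ± 0.14 and aldose reductase Akr1b1 rose (1.82 ± 0.09). Hspa4l fell (-0.38 ± 0.10), but was at 0.23 with library size alone (adjusted p = 0.0597). Cell cycle genes comprised 19 higher, 2 lower and 5 not called (median 0.83, camera adjusted p = 0.0195, and adjusted p = 0.614 with an estimated correlation). Cenpf rose (1.26 ± 0.17), and Kif11 and cyclin D1, Ccnd1, fell by 1.32 ± 0.14 and 1.72 ± 0.19. Tyms was at -0.24 ± 0.15 (adjusted p = 0.167), and at 0.37 with library size alone (adjusted p = 0.0364). The p53 and apoptosis genes comprised 11 higher, 5 lower and 3 not called (median 0.36, camera adjusted p = 0.102, and adjusted p = 0.235 with an estimated correlation), with Bak1 and Cdkn1a at 1.29 ± 0.08 and 2.48 ± 0.20 and Ccng1 at -0.93 ± 0.10.

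Markers of blood, fat, muscle, adrenal and urothelium comprised 1 higher, 1 lower and 9 not called (median 2.94, camera adjusted p = 0.762, and adjusted p = 0.908 with an estimated correlation). The muscle genes Acta1 and Mylpf were at 2.94 ± 0.51 (3.71 without WT replicate 2) and -1.80 ± 0.34. The fat droplet gene Plin1 was at 6.87 ± 2.87 (adjusted p = 0.0533), which rested on 97.6 CPM in HOMO replicate 1, and without that library Plin1 was at 2.09 (adjusted p = 0.455). Plin1 was called without HOMO replicate 3 (7.28, adjusted p = 0.0394) or HOMO replicate 4 (7.27, adjusted p = 0.0417) and with library size alone (7.48, adjusted p = 0.0356). The erythroid gene Alas2 was at -1.15 ± 1.13 (adjusted p = 0.381), and at 0.48 without WT replicate 4. The fat marker Fabp4 stood at 768 CPM in HOMO replicate 1 and 273 CPM in HET replicate 1, against 7.55 to 28.3 CPM in the other 10 libraries. Without both of these libraries, 10819 genes were called in HOMO against WT.

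Among the 10 largest rises, the matrix metalloproteinase Mmp7 had 1 count in WT and 10093 in HOMO, a ratio of 6828 (95% interval from 1226), and the neutrophil chemokine Cxcl6 1 and 4516, a ratio of 3055 (from 548). Draxin had 0 counts in WT and was at least 237-fold higher in HOMO. The tryptophan dioxygenase Tdo2 and the deiodinase Dio3 had ratios of 1217 (from 218) and 643 (from 178). The scavenger receptor Cd163 rose by 10.25 ± 1.15 and the diamine oxidase Aoc1 by 9.49 ± 0.34 on the log2 scale (largest adjusted p = 1.59e-05). The carbonic anhydrase Ca3, abundant in fat and muscle, was at 8.66 ± 2.72 (adjusted p = 0.0158) and at 5.88 without HOMO replicate 1 (adjusted p = 0.0433), which held 1387 CPM, and limma voom did not call it (adjusted p = 0.0610). Plin4 had a ratio of 482 (165 to 2336) and an adjusted p of 0.0378, with 42.6 CPM in HOMO replicate 1, and its log2 fold change of 8.51 was 4.26 without that library (adjusted p = 0.210). Plin4 also lost its call without any 1 WT library (8.08 to 9.53), without a filter (8.51) or with limma voom (5.65).

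Among the 10 largest falls, the kidney androgen-regulated protein Kap went from 6706 CPM in WT to 27.7 ± 24.6 CPM in HOMO (-7.92 ± 0.90). The kallikreins Klk1c10 and Klk1c2, whose counts are uncertain, were at least 195-fold lower and lower by a ratio of 492 (from 88.3). Mbl1, a mannose-binding lectin, was at -7.61 ± 0.64 and Akr1c12l1, also uncertain, at -7.81 ± 1.06. The anion transporter Slco1a1 (-12.06 ± 1.59), Cacng5 (-9.14 ± 1.73), Olr1668 (-8.60 ± 1.999, uncertain), the cytochrome Cyp1a1 (-7.96 ± 1.73) and Slc7a12 (-7.86 ± 1.505) had edgeR adjusted p-values of at most 0.00300, and limma voom called none of these 5 (adjusted p 0.0540 to 0.148). Without HOMO replicate 1, Cacng5, Olr1668 and Cyp1a1 were at -9.85, -9.21 and -8.65, and Olr1668 was at -7.88 without WT replicate 3. Slco1a1 ranged from 6.22 to 206 CPM among the WT libraries.

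**Figure D3:**
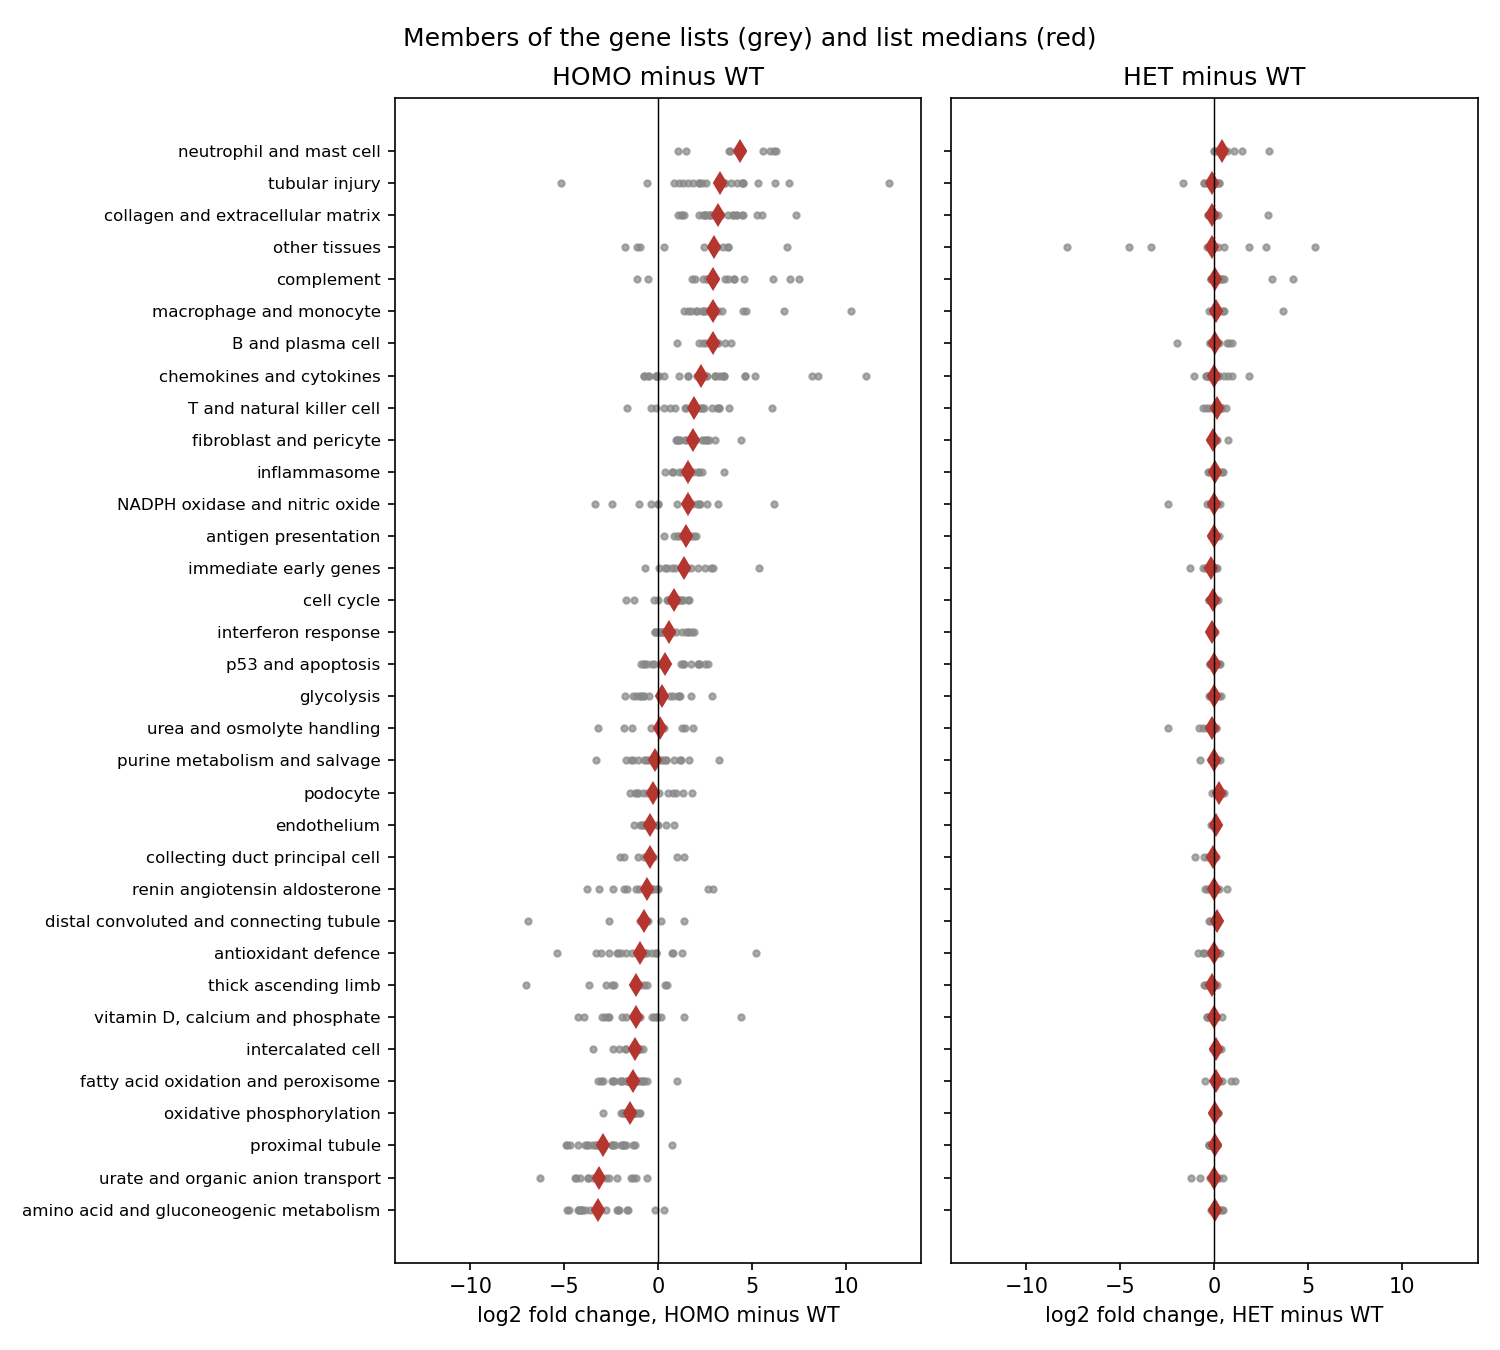
Log2 fold change (horizontal axes) of the tested members (grey points) and the median (red diamonds) of each of the 34 lists (vertical axis), for HOMO minus WT on the left and HET minus WT on the right. HOMO medians ran from -3.19 for amino acid and gluconeogenic metabolism to 4.32 for neutrophil and mast cell genes, and with library size alone those of the purine, collecting duct, podocyte, endothelium and renin lists turned from below to above 0.

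The comparison of HET with WT addressed whether 1 mutated allele is enough to change the kidney cortex. No gene passed the threshold in HET kidneys, Xdh included. The proximal tubule list, with a median log2 fold change of -2.96 in HOMO, was at 0.02 in HET, and the macrophage list at 0.07 against 2.92. In edgeR 0 of 15856 genes were called, and 318 (2.01%) had an unadjusted p under 0.05. That share is smaller than the level itself gives for unchanged genes, so the absence of calls does not exclude changes. DESeq2 called 0 genes with 330 at that unadjusted level and limma voom 0 with 236. The HET and WT libraries did not overlap for 257 genes (1.62%, where chance gives 2.86%). The authors' deposited values call 1 of the 12759 genes tested there, LOC100909505 (log2 fold change 7.15, false discovery rate 4.76e-08), and Xdh is at -0.75 with a false discovery rate of 0.0970.

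Camera called 6 of the 34 lists in HET against WT, and each had an adjusted p of 0.925 with an estimated correlation. Podocyte genes (median 0.24, camera adjusted p = 8.63e-04) and fatty acid oxidation genes (median 0.09, adjusted p = 0.0373) had higher values. Collecting duct principal cell genes (median -0.08), collagen and extracellular matrix genes (-0.13) and interferon response genes (-0.11), each at a camera adjusted p of 0.0461, and cell cycle genes (-0.08, adjusted p = 0.0373) had lower values. Adjusted over the list alone, 1 member of these lists was called, Aqp4 (-1.02 ± 0.26, adjusted p = 1 over all genes), a water channel of the collecting duct that was at 6.51 ± 1.83 CPM in HET and 13.2 CPM in WT. Of the podocyte genes, Wt1 was at 0.42 ± 0.18, Synpo at 0.41 ± 0.20, Nphs1 at 0.34 ± 0.20 and Tcf21 at -0.12 ± 0.19. In the other collecting duct genes, Fxyd4 was at -0.54 ± 0.28, Avpr2 at -0.12 ± 0.12 and Gata3 at 0.09 ± 0.18. Matrix genes included Postn at 2.83 ± 1.34, with 15.7 CPM in HET replicate 1 and at most 0.429 CPM in the other HET libraries (-1.33 without HET replicate 1), Thbs2 at -0.36 ± 0.26, Dcn at -0.22 ± 0.16 and Col4a1 at 0.08 ± 0.18. Interferon genes included Ifih1 (-0.18 ± 0.12), Stat2 (-0.12 ± 0.08), Irf7 (-0.25 ± 0.20) and Ddx58 (0.04 ± 0.14). Fatty acid oxidation genes included Acaa1a (0.20 ± 0.13), Pdk4 (1.08 ± 0.69), Eci1 (0.41 ± 0.29) and Acox2 (-0.52 ± 0.43), and cell cycle genes Mcm4 (-0.23 ± 0.22), Ccnd1 (-0.20 ± 0.19), Mcm7 (-0.13 ± 0.12) and Bub1b (0.18 ± 0.27). Gata3, Tcf21, Col4a1, Ddx58 and Bub1b also changed sign without some single library. The number of lists called fell to 3 without WT replicate 4, HET replicate 1 or HET replicate 2, and fry called 0. With 1 of the 8 libraries left out, the podocyte list kept its call each time, and the call was lost in 4 fits for fatty acid oxidation, 5 each for collecting duct and cell cycle, and 6 each for collagen and interferon. The podocyte means relative to WT still overlapped, from -0.239 to 0.398 in WT libraries and from -0.0521 to 0.496 in HET libraries. The fatty acid oxidation means relative to WT were 0.326 and 0.362 in HET replicates 1 and 2 and -0.0567 and -0.0755 in HET replicates 4 and 5, and the call was lost without HET replicate 1 (adjusted p = 0.366) or HET replicate 2 (0.745).

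The HET and HOMO effects against the same WT libraries had a correlation of 0.178 across genes and a covariance of 0.117, where 20 simulations of unchanged groups gave 0.501 ± 0.0188 and 0.0553 ± 0.00267, a covariance difference of 0.0618. In the simulations HOMO was unchanged too, whereas 71.7% of genes were called in the real HOMO against WT. Those changes widen the spread of the HOMO effects and lower a correlation, so 0.178 cannot be set against 0.501. With the WT libraries split into 2 and 2, the correlation ran from 0.0586 to 0.223 and the covariance from 0.0460 to 0.187 over 6 splits. Fat markers were high in both HET replicate 1 and HOMO replicate 1, whose deviations from their group means correlated at 0.440 across genes. Splitting WT does not remove what these libraries share. The covariance without them was not computed, so it cannot be read as a shared effect of the mutated allele. Libraries of the same group differed in genes of the straight part of the proximal tubule, a set of 8 chosen after the data were seen, of which 3 are in the fixed lists. Their mean log2 CPM ran from 2.10 in WT replicate 2 to 7.41 in WT replicate 3 and from 3.52 in HET replicate 5 to 7.11 in HET replicate 4. Over the 8 WT and HET libraries this mean correlated with that of the thick ascending limb list (r = 0.879, exact permutation p = 0.00479, adjusted 0.00718; rho = 0.952, exact p = 0.00114, adjusted 0.00342). It was inversely related to that of 6 convoluted segment genes (r = -0.952, exact permutation p = 2.98e-04, adjusted 8.93e-04; rho = -0.881, exact p = 0.00724, adjusted 0.0109). Without WT replicate 2 and HET replicate 5, r was 0.892 and -0.860. These are 2 of 3 relations computed, the other being with library totals (r = 0.414, exact permutation p = 0.312, adjusted 0.312; rho = 0.190, exact p = 0.665; r = -0.340 without those 2 libraries). No batch is given in the labels.

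**Figure D4:**
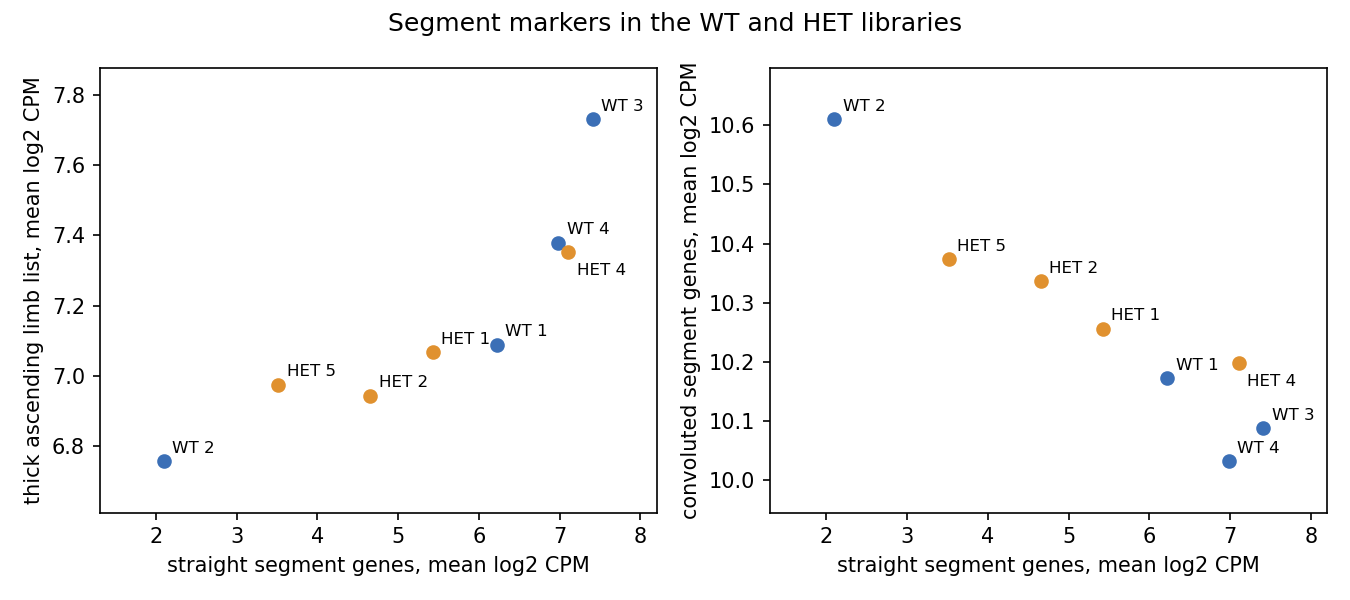
Mean log2 CPM of the thick ascending limb list (left, vertical axis) and of 6 convoluted segment genes (right, vertical axis) against that of 8 straight segment genes (horizontal axes), 1 point per WT or HET library. WT replicate 2 has the lowest straight segment value (2.10) and WT replicate 3 the highest (7.41), and each value is a level within a library on the TMM scale.

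The comparison of HOMO with HET addressed the difference between 2 mutated alleles and 1 among littermates. As in the comparison with WT, proximal tubule genes were lower in HOMO than in HET (27 of 28, median -3.02) and genes of macrophages (20 of 20, median 2.90) and of collagen and matrix (27 of 27, median 3.24) were higher. The direction of the proximal tubule list held with library size alone. That scale moves all genes upward, so the rises could not turn there. These 3 lists had camera adjusted p-values of 4.31e-11, 1.08e-08 and 1.51e-09, and adjusted p-values of 0.0610, 0.223 and 0.226 with an estimated correlation. Of 15856 genes, 11199 were called, 5733 higher and 5466 lower, 5778 by more than 2-fold. With library size alone 10380 of 12894 called genes (80.5%, against 51.2%) were higher, with a median of all genes of 0.67 and 1054 shared calls in opposite directions. The groups did not overlap for 10215 genes (64.4%, where chance gives 2.86%). The authors' deposited table calls 9022 of the 13845 genes tested there, 4746 higher and 4276 lower, of which 8917 were called here in the same direction. Of the genes called in HOMO against WT, 5424 were higher and 5207 lower here too, against 2119 and 1899 for independent lists, with 0 in opposite directions. The HOMO libraries are shared, so independent lists are not the proper yardstick. In 20 simulations of unchanged groups 0 genes were called in both, and the correlation of fold changes was 0.478 ± 0.0203, where 0.973 was observed. No gene is changed there, so hardly any call is possible, and neither that count nor that correlation measures what sharing adds in the real data. With the HOMO libraries split into 2 and 2, so that no library was shared, 4640 to 4724 genes were higher and 4471 to 4559 lower in both over 6 splits, with 0 to 11 in opposite directions. Camera called 24 lists, the 23 of HOMO against WT in the same directions and the renin list, and none with an estimated correlation (smallest adjusted p = 0.0610).

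Xdh in HOMO was at -0.73 ± 0.43 against HET (adjusted p = 0.151), and at -1.50 without the library labelled HOMO replicate 3 (adjusted p = 1.24e-05). With all libraries, limma voom called Xdh (-1.01, adjusted p = 0.0257), and with library size alone Xdh was at -0.09 (adjusted p = 0.856). Mmp7 had 0 counts in HET and was at least 1968-fold higher in HOMO. Tdo2, the cytokine Il24, the protease Prss22 and Dio3 had 1 to 3 counts in HET and ratios of 1052 (95% interval from 189), 759 (from 260), 870 (from 156) and 371 (from 127). Aoc1 rose by 9.29 ± 0.34, Cxcl6 by 9.24 ± 0.55, the keratin Krt17 by 8.76 ± 0.87 and the matrix-associated genes Cthrc1 and Sfrp4 by 8.83 ± 0.62 and 8.47 ± 0.98 (largest adjusted p = 1.42e-05). Cxcl6 was at 10.73 without HET replicate 5, and Cthrc1 and Sfrp4 at 9.47 and 9.76 without HET replicate 1. Of the largest falls, Klk1c10 was at least 212-fold lower and Klk1c2 lower by a ratio of 521 (from 93.6). The fatty acid hydroxylase Cyp4a2, uncertain because of its paralogs, was at -7.57 ± 0.44, the trypsin inhibitor Spink1 at -7.62 ± 0.29, the thioesterase Acot12 at -7.46 ± 0.34, Kap at -7.85 ± 0.90 and Mbl1 at -7.59 ± 0.64 (largest adjusted p = 1.54e-05). Slco1a1, Cacng5 and Akr1c12l1 were at -11.55 ± 1.59, -8.76 ± 1.72 and -7.36 ± 1.04, and stood at -10.92, -7.37 and -6.66 without HET replicate 4. Cacng5 was at -9.47 without HOMO replicate 1, and limma voom did not call Slco1a1 (adjusted p = 0.0870) or Cacng5 (adjusted p = 0.149).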

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

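Of the tests in this part, those of the label and of mixing for Xdh in the library labelled HOMO replicate 3 and that of depth for straight segment genes were written after the result was seen, and the tests of cell-type share and of segments were written with single members already seen. A library lay far from its group, by Dixon's ratio, in 47 of 465 groups of 4 values (10.1%), where about 5% are due by chance. In HOMO replicate 1, Ca3 (1387 CPM, others at most 94.4), Plin4 (42.6), Plin1 (97.6) and Sod1 (267) were high. In HET replicate 1, Ca3 (206 CPM, others at most 0.674), Plin4 (17.8), Plin1 (33.6), Cd163 (2.12), Postn (15.7), Alas2 (11.3), Irf1 (24.7) and Ctsz (18.5) were high, and so was Ier3 (29.6) in HET replicate 2. In HET replicate 4, Cacng5 (145 CPM), Olr1668 (26.6), Slc7a12 (131), Tff3 (785), Slc34a2 (41.5), Ace (6.94) and Cd3g (1.22) were high, and Slc22a8 (1101) and Ccng1 (143) low. In WT replicate 2, Slc22a8 (1609 CPM), Kl (651), the mitochondrial share (17.0%) and the share of the 10 largest genes (19.9%) were high, and Cyp4a2 (1374 CPM) low. Jchain (1.40 CPM) and Aqp11 (52.4) were low in WT replicate 3, and Alas2 (15.0) was high in WT replicate 4. In HOMO replicate 4, Lcn2 (661 CPM), Lox (122), Tgfb1 (70.7), S100a8 (63.2), S100a9 (111), C1qa (261), Eno1 (721) and Synpo (68.2) were high, and Aoc1 (22.3), Rhbg (13.1) and Mcm7 (43.1) low. In the library labelled HOMO replicate 3, Xdh (230 CPM, others 57.6 to 61.7), Klk1 (12.6), Nphs1 (50.5), Gpx3 (3842) and Acaa1a (50.5) were high, and Irf1 (61.3) low.

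Xdh stood at the WT level in the library labelled HOMO replicate 3, although flags of this kind are due by chance in about 5% of groups. A WT or HET rat under a HOMO label was argued against by 11215 other genes, which put this library at 0.921 on a scale from the WT mean (0) to the mean of the other HOMO libraries (1), where those lay at 0.933 to 1.07 and the WT and HET libraries at -0.0470 to 0.0615. WT kidney RNA mixed into the library was argued against by a median share of -0.00287 (largest 0.197) over 167 genes with at least 100 CPM in WT that fell over 8-fold, where Xdh would need 0.752. A joint rise of the chromosome region was argued against by a median log2 difference of -0.144 (-1.36 to 0.45) of the 10 nearest genes. A change limited to Xdh would not show in those genes. More inflammation in this library predicted a mean log2 CPM over the chemokine and interferon lists above that of each other HOMO library. The mean was 3.86, below the 4.01 to 4.19 of the other HOMO libraries, which argued against more inflammation as these lists together measure it. Relative to WT, this library was the lowest of the HOMO group for interferon genes (0.202 against 0.633 to 0.955). The same held for T and natural killer cell genes (1.46 against 1.85 to 1.97). It was also lowest for B and plasma cell (2.12), neutrophil and mast cell (3.48), complement (2.92) and antigen presentation genes (1.04). The chemokine (2.11), macrophage (3.26) and immediate early (1.90) lists lay between those of the other HOMO libraries. This library was the highest in none of these lists. A different mutated allele, or an edited transcript that escapes decay, remains open and was not tested.

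Genes of immune cells, fibroblasts and injured tubules were higher in HOMO. A smaller share of proximal tubule RNA, raising all other cell types alike, was argued against by the distal, collecting duct, podocyte and endothelium lists, whose lowest median log2 fold change was -0.74 where the macrophage median was 2.92. With library size alone these lists were at -0.13, 0.16, 0.33 and 0.18 and the macrophage list at 3.53. A change of scale moves all lists by about the same amount, so the gap could not have closed there and adds no support. Library size alone moves all genes of HOMO against WT upward, so the macrophage value cannot tell whether the choice of composition factors adds to the rise. The genotype is the difference that the design gives, and whether more cells of these types or more RNA per cell underlies the values was not tested.

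Straight segment genes differed between libraries of the same genotype. Adjusted over the 3 relations computed, the exact permutation p was 0.00718 for the thick ascending limb list and 8.93e-04 for convoluted segment genes. That adjustment does not cover the choice of genes, made after the data were seen, so chance remains possible for each. A dissection reaching to different depths was supported by the correlation of 0.879 with the thick ascending limb list. A shift between proximal tubule segments predicted the correlation of -0.952 with convoluted segment genes. Different depths of dissection would give that correlation too, so it does not tell these explanations apart. The correlation with sequencing depth, 0.414 (exact permutation p = 0.312), is too uncertain with 8 libraries to decide on depth. Differences in maturity or in androgen exposure between rats remain open and were not tested. Each HOMO library lay below each WT and HET library in straight segment genes (-2.86 to 1.31), the thick ascending limb list (4.81 to 5.66) and convoluted segment genes (7.19 to 7.75). Whether different depths of dissection added to the lower straight segment and thick ascending limb values in HOMO was not tested.

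All splits of the 8 libraries of a comparison into 4 and 4 were fitted, 35 per comparison. In HOMO against WT 1 of 35 splits, the real grouping with 11369 genes, called as many genes, and the highest other split called 0. In HOMO against HET it was also 1 of 35, with 11199 genes and at most 1 gene in another split. In HET against WT the real grouping called 0 genes, which all 35 of 35 splits reach whatever the data, so this count says nothing about chance. The highest split there, WT replicates 1, 3 and 4 with HET replicate 4 against the others, called 176 genes, which points to a structure of the samples that follows the straight segment values.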

How the results depend on the processing

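Under the other settings, including each library left out, HOMO against WT called 10558 to 12856 genes (11369 reported), HOMO against HET 10450 to 12894 (11199) and HET against WT 0. At a level of 0.01 the counts were 9805, 9635 and 0. Against a fold of 1.5 they were 6606, 6520 and 0, since that test asks for a larger change. Leaving out 1 library gave 10926 to 11339, 10743 to 11178 and 0 to 0 genes, and Xdh log2 fold changes of -2.25 to -1.28 (HOMO against WT) and -0.87 to -0.58 (HET against WT). Library size alone moved all genes of HOMO against WT upward, their median from 0.04 to 0.65, and with that shift Xdh was at -0.85 and not called. Of the 23, 6 and 24 lists called by camera (HOMO against WT, HET against WT, HOMO against HET), 0, 0 and 0 kept the call with an estimated correlation, which widens the test where members vary together. Fry called 30, 0 and 30, and leaving out 1 library gave camera counts of 22 to 25, 3 to 7 and 24 to 25. Fry asks whether members of a list changed, whereas camera asks whether they changed more than other genes. With 71.7% of all genes called in HOMO against WT, the fry calls there add little to those of camera. The same shift took Tyms (0.37) and Hspa4l (0.23) from below to above 0. Fry gave the urea and osmolyte list in HOMO against HET the opposite direction to camera (fry adjusted p = 1.95e-05). Camera had not called that list (adjusted p = 0.922), whose members comprised 3 higher, 3 lower and 3 not called. The cause was not tested. Of 2137 gene values under alternatives in HOMO against WT, 2098 stayed called or uncalled as reported (1 with a turned sign), 34 lost the call, 3 gained it and 2 are those given above; in HET against WT all 384 stayed uncalled, 12 of them in 6 genes with a turned sign, and in HOMO against HET 332 of 336 kept direction and call. With the replicate number as a block the counts were 11265, 0 and 10805 genes and 24, 5 and 24 lists, and Xdh was at -1.78 and -0.58. Of the 6 lists reported for HET against WT, 4 were among those 5. The pairing of equal numbers was not borne out, since correlations of 10 pairs ran from -0.133 to 0.440 and 2 of 12 libraries correlated best with their own number. Settings added after the data were seen gave 10819, 0 and 10339 genes without HOMO replicate 1 and HET replicate 1, 0 genes in HET against WT with a straight segment covariate, and 0 genes with Xdh at -0.75 there without the library labelled HOMO replicate 3. Depth limits genes below 3 counts, which correspond to 0.184 CPM in the smallest library.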

Other observations

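Markers of fat and of the urothelium, the lining of the renal pelvis, were examined after the data were seen. Fat markers were high in HOMO replicate 1 and HET replicate 1. The adipokine gene Adipoq was at 319 and 76.4 CPM there and at 3.86 to 9.50 CPM in the other libraries, and the brown fat gene Ucp1 at 20.1 and 37.6 CPM there, at 7.79 CPM in HOMO replicate 2 and at most at 0.465 CPM in the other libraries. Adipsin, Cfd, was at 293 CPM in HOMO replicate 1 and 35.015 CPM in HET replicate 1, and at 24.0 to 31.7 CPM in the other HOMO libraries against 0.265 to 1.02 CPM in WT. The uroplakins Upk1a, Upk3a, Upk2 and Upk1b were at 46.7, 30.7, 32.7 and 29.5 CPM in HOMO replicate 1 and at most 3.97 CPM in any other library.

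LOC100909505 (ENSRNOG00000046159, chromosome 7), which the authors' deposited values call in HET against WT, had 182, 144 and 107 counts in HET replicates 1, 2 and 5 and 95 counts in HOMO replicate 2. The other 8 libraries had 0 or 1 count each. In the fit used here it was at 7.18 ± 2.09 (edgeR adjusted p = 1).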
